A study of Homo sapiens with 3 samples.

How the data were processed

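RNA from 3 cultures of the human malignant mesothelioma line H28 was measured on one-colour arrays, with 1 array for the parental line and 1 for each of 2 resistant clones. Total RNA was amplified and labelled with Cy3, per the labels' protocols. The spot intensity values deposited in the scanner files were background-subtracted and detrended within each array by Feature Extraction, per the file headers, and were not scaled between arrays. The headers name Feature Extraction version 10.7.1.1, whereas the submitters' processing notes name version 9.5.1.1, and the difference was left unresolved. All 3 arrays shared 1 slide and 1 scan, so slide and scan gave no batch to test. Probe positions are those of the hg19 build, per the file headers.

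The deposited table of the whole series holds intensity values on a linear scale. Its sorted values were the same in the 3 columns within 0.0353%, which is the mark of quantile normalization. Each column correlated with its own array's log2 signal at r of at least 0.99995, against at most 0.987 for another array, across probes, and each column had a median of 12.6. How the authors set its scale is not given in the sources used here, and it served as an alternative.

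Each array held 60901 non-control spots of 58201 probes. Spots well above background numbered 28727 (47.2%) on the parental array, 28288 (46.4%) on the array of clone A1 and 28504 (46.8%) on the array of clone B1. No spot was saturated, and 66, 77 and 55 outlier spots were left out. The 300 probes printed as 10 spots had a median SD between spots of 0.06, 0.05 and 0.05 on the log2 scale, which covers error within an array only. The number of arrays limits the precision.

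Processed signals were put on the log2 scale, scaled by subtracting each array's 75th percentile over non-control spots, and averaged over the spots of a probe. Names were updated through RefSeq: 31100 probes were named by accession, 3369 by symbol and 497 by an older symbol, 178 kept the name in the file, and 23057 had no gene name. The 35144 named probes covered 23702 genes, and the probe of highest mean signal stood for its gene. Of the 565 called genes with a 2-fold change and several probes, 47 (8.32%) had probes of opposite sign.

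Genes were tested where their probe was well above background on the parental array or on both clone arrays, which left 15393 genes. The fit used lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. It had 1 residual degree of freedom, from the 2 clones, and 10.7 in all after moderation across genes. The single parental array was assumed to vary like the clones. The labels call the resistant samples clones and do not say that cultures were repeated, so p-values measure only the spread between these samples. A second measure needed no test: a gene counted when it differed by at least 2-fold in the same direction in both clones. Single pairs of arrays were compared by size alone. A gene not well above background on any array of a group has only a bound there, given as "at least N-fold", where the dim side was set at the higher of its own signal and the lowest signal among probes well above background on each array.

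The 44 gene lists were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and limma's fry served as alternatives. Both rest on the 1 residual degree of freedom, so a list could hardly pass them after adjustment over 44 lists. For each clone, the percentile of a list's median among 10000 random lists matched on signal in 20 bins was also computed. The rule for named genes was fixed then too. It took the 12 highest and 12 lowest genes measured on all 3 arrays, ranked by the smaller of the 2 clones' differences, and the 5 highest and 5 lowest bounds. Between the clones it took the 8 highest and 8 lowest genes and 3 bounds each way, plus genes that moved 2-fold in opposite directions. Members of the fixed lists could also be named, and a list was described where camera called it, where at least 3 members differed by 2-fold in both clones, or where it bears on the question of the study. Some sex-linked genes were left out of the rule, and some list members are not reported here.

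The steps were tested on simulated data made from the means and spread of these 15393 genes, for the comparison of resistant clones with parental cells, over 20 runs. With 200 genes changed and each gene's own variance, limma recovered 23.1% of genes changed by 0.50 on the log2 scale, 75.4% at 1.00, 95.3% at 2.00 and 99.0% at 4.00. The 2-fold rule recovered 1.1%, 32.2%, 98.8% and 100% of them. False calls made up 13.7% of all calls there, and 17.1% with variances drawn from the fitted prior, above the nominal 5%. With the prior known instead of estimated, they made up 1.28% and 4.74%. The prior degrees of freedom, 9.71 in these data, came out anywhere from 7.26 upward in the runs drawn from that prior, so a single residual degree of freedom estimates them poorly. With 5000 genes changed, nearer to the number called here, false calls made up 3.7% and 3.87%. All 3 simulated arrays of a gene had the same variance. These shares therefore hold only if the parental array varies like the clones, which 1 parental array cannot show. The runs with 200 genes changed held a planted list of 20 genes and a planted run of 80 neighbouring genes. Both were found in 20 of 20 runs, and unchanged lists and gene orders in 0. The list was shifted by 1 on the log2 scale and the run by 0.6, and smaller shifts were not tested. Genes were simulated independently, so the preset correlation of 0.01 was not tested on co-regulated lists. Adjustment over 44 lists and the rule that a window passes in both clones were not tested either. A shuffled gene order seldom passes a threshold from shuffled orders, so that 0 follows from the design.

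Alternatives covered the scaling, the background correction (normexp with an offset of 50), the deposited table, the filter on dim probes, the probe rule, the fit, the fold minimum and each clone left out. Several further ones were chosen after seeing the data. Text tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.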

Results

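Gene expression was measured in H28, a line derived from human malignant mesothelioma, and in 2 clones of it, H28-cSR-A1 and H28-cSR-B1, here A1 and B1. The clones resist cSBL, a sialic acid-binding lectin with ribonuclease activity from bullfrog eggs, to which the parental cells are sensitive. The series title describes cells kept under treatment with the lectin, but the labels do not say whether the clones were grown with it when RNA was taken. The parental line was measured on 1 array and each clone on 1 array, so the resistant group has n = 2 and the parental group n = 1. Each array held 60901 non-control spots, of which 46.4% to 47.2% were well above background. Values below are differences of log2 signal, resistant minus parental, with the SD between the 2 clones, and adjusted p-values are from limma. The SD holds no error of the single parental array, so it understates the uncertainty of a difference. For ITGB4, the SD was 0.01 and limma's SE 0.14.

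The first comparison asked which genes differed between the resistant clones and the parental cells. Among genes well above background on all 3 arrays, the lowest were aldo-keto reductases, AKR1B15 and AKR1B10, enzymes that reduce aldehydes and ketones. AKR1B10 was lower by 603-fold (-9.24 ± 0.48, SD, n = 2; adjusted p = 1.61e-09) and AKR1B15 by 641-fold (-9.32 ± 0.53; adjusted p = 2.69e-09). AKR1C8 (-6.62 ± 0.04), AKR1C1 (-5.89 ± 0.01) and AKR1C4 (-4.68 ± 0.12) were lower too. These paralogs are alike in sequence and may share signal, so the value of each single gene is uncertain. The probe of AKR1B10 lies on chromosome 7 at 134225939 to 134225998 and that of AKR1C1 on chromosome 10 at 5019910 to 5019969.

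Outside this family, RARRES2, which encodes the secreted protein chemerin, fell by 7.14 on the log2 scale (SD 0.19), and PEBP1, an inhibitor of Raf kinase, fell by 6.28 (SD 0.14). The hormone gene SST (-5.67 ± 0.25), the small heat shock protein gene CRYAB (-5.65 ± 0.60), AMBP (-5.02 ± 0.20), MAP2 (-4.87 ± 0.39) and PLCD4 (-4.78 ± 0.15) were also among the 12 lowest. Of genes well above background in the parental cells and on neither clone array, the surface glycoprotein gene THY1 was at least 398-fold lower, the transporter gene SLC47A2 at least 174-fold, APCDD1L-DT at least 97.3-fold, KIAA0319 at least 71.6-fold and the carbonyl reductase gene CBR1 at least 31.5-fold. Their adjusted p-values ranged up to 1.29e-06, that of CBR1.

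In the other direction, TNFRSF6B, a decoy receptor that binds Fas ligand, was 89.0-fold higher in the clones (6.48 ± 0.21; adjusted p = 2.69e-09), with its probe on chromosome 20 at 62328874 to 62329690. The water channel gene AQP1 rose 70.2-fold (6.13 ± 0.62) and the troponin gene TNNT1 53.7-fold (5.75 ± 0.13). IGF2, a growth factor gene, rose 47.6-fold (5.57 ± 0.32), and IGFALS, whose product carries such factors in serum, rose 50.4-fold (5.66 ± 0.99; 6.35 in A1 and 4.96 in B1). The integrin gene ITGB4 (5.52 ± 0.01), the chemokine gene CCL2 (5.39 ± 0.26), the EGF receptor ligand gene AREG (4.93 ± 0.40), TUBA8 (4.76 ± 0.01), ICAM1 (4.63 ± 0.06) and HSD17B2 (4.93 ± 0.65) rose as well. GNE, whose product makes the precursor of sialic acid, rose 32.6-fold (5.03 ± 0.58; adjusted p = 4.94e-07), with its probe on chromosome 9 at 36214642 to 36214701. Of genes not well above background in the parental cells, LIPC was at least 216-fold higher in the clones, FLG at least 121.5-fold, TNC at least 89.5-fold, EDN1 at least 62.8-fold and the immunoproteasome gene PSMB8 at least 40.6-fold. These limits use the mean of the clones, which lay apart for some genes: in A1 and B1 alone they were 320 and 146 for LIPC, 76.3 and 194 for FLG, and 38.7 and 102 for EDN1. Other probes of some named genes gave smaller differences in the same direction: 5.61 for TNFRSF6B, 4.16 for AQP1, 4.33 and 6.62 for FLG, 4.59 for EDN1 and -4.97 for PEBP1. The other probes of APCDD1L-DT ranged from -7.30 to -4.87.

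Across the 15393 genes tested, 5169 passed the threshold in limma, 2542 higher and 2627 lower in the clones, and 1138 and 1148 of these differed by at least 2-fold. The median SE was 0.19. By size alone, 2059 genes differed by at least 2-fold in the same direction in both clones, 1006 higher and 1053 lower. Simulated unchanged arrays that shared the parental array, all with the same variance for a gene, gave 36.8 such genes on average and at most 53 in 100 runs. The split of calls depended on the scaling: relative to the spike-in RNAs the median of all genes lay at 0.36 (0.18 in A1 and 0.58 in B1), where 916 genes were called higher and 409 lower, and 1596 and 575 differed by at least 2-fold in both clones. Only 1386 genes were called when the single parental array was given 4 times the clones' variance, an alternative chosen after seeing the data like the spike-in scaling.

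**Figure D1:**
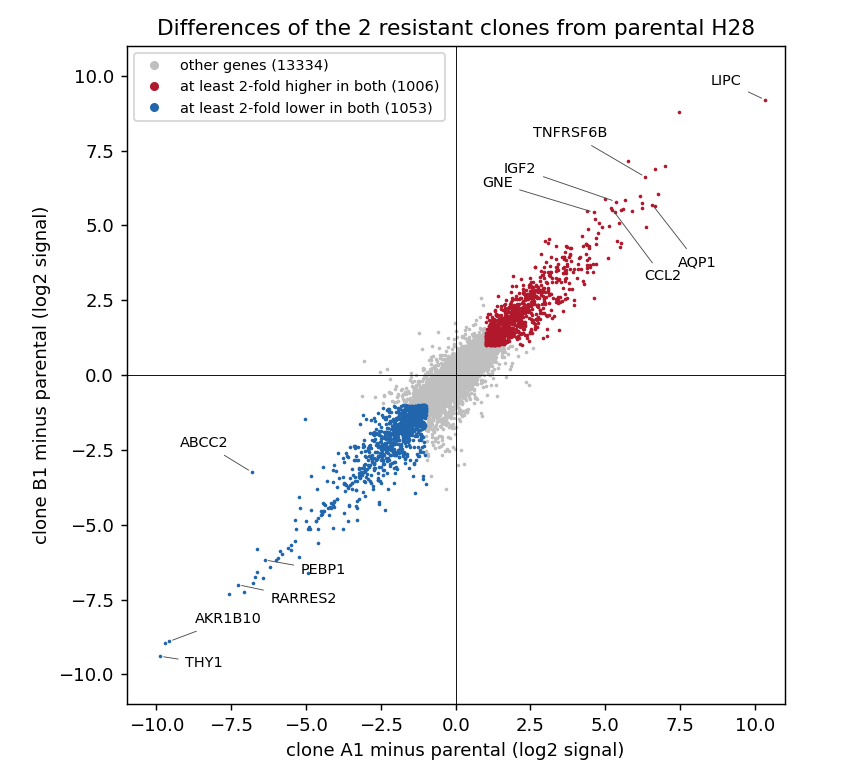
Log2 signal of clone A1 minus parental (horizontal axis) against clone B1 minus parental (vertical axis) for the 15393 genes tested, 1 point per gene. The 1006 genes at least 2-fold higher in both clones are red, the 1053 lower in both are blue, and most points lie near the diagonal.

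Both clones differed from the parental cells in much the same way. In A1, 2768 of 15623 genes compared differed by at least 2-fold (1405 higher, 1363 lower), and in B1 2835 of 15668 (1421 higher, 1414 lower). With scaling to the median these splits were 1310 higher and 1461 lower in A1, and 1632 and 1243 in B1. Across genes, which are not independent replicates, the differences of the clones correlated at r = 0.933, with a covariance of 0.899. Unchanged arrays sharing the parental array, simulated with equal variance on all arrays, gave 0.50 and 0.0446, a difference in covariance of 0.855. Among the 15393 genes tested, where 1006 higher and 1053 lower genes were shared, independent lists would share 99.9 and 125. The single parental array could not be split, so part of the excess over those numbers may come from sharing it. ADCY10P1 was the only gene at least 2-fold apart from parental in opposite directions (-1.22 in A1, where it was not well above background, and 1.40 in B1).

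The list of NRF2 targets and aldo-keto reductases was lower in the clones (camera adjusted p = 8.19e-17, and 0.787 with an estimated correlation). Camera with an estimated correlation rests on 1 residual degree of freedom, where even the unadjusted p of this list was 0.0654. Its adjusted p of 0.787, here and below, therefore says little for or against a list. The preset correlation of 0.01 is assumed, and genes of a list are not replicate cultures, so a small camera p there is no measure of replication. Of the 23 tested members of the NRF2 list, 20 fell, 0 rose and 3 did not pass, and 15 fell by at least 2-fold in both clones. Adjusted over the list alone, 21 passed. Its aldo-keto reductases were listed with knowledge of the study. Neither their count nor the camera p of the whole list is therefore independent evidence of the direction. Camera was not run without these reductases. Beyond them, the transporter gene ABCC2 (-5.03 ± 2.53), the sulfiredoxin gene SRXN1 (-2.60 ± 0.05), the haem oxygenase gene HMOX1 (-2.27 ± 0.27), the glutathione synthesis gene GCLC (-1.67 ± 0.01) and NQO1 (-1.29 ± 0.17) fell.

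Targets of p53 were lower as a list (camera adjusted p = 5.61e-07; adjusted p = 0.787 with an estimated correlation). Of 20 tested, 16 fell and 0 rose, 10 of them by at least 2-fold in both clones, and 16 passed when adjusted over the list alone. TP53I3 (-2.40 ± 0.03), FDXR (-2.34 ± 0.33), the cell cycle inhibitor CDKN1A (-2.30 ± 0.38) and ZMAT3 (-1.69 ± 0.19) were among them. Among BCL2 family and apoptosis genes, 10 of 29 rose and 4 fell, 14 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.138). CASP4 (2.37 ± 0.08) and the inhibitor of apoptosis BIRC3 (1.53 ± 0.11) rose, whereas the BH3-only genes BCL2L11 (-1.72 ± 0.14) and HRK (-1.35 ± 0.32) fell.

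Genes for the sialic acid that the lectin binds were not called as a list (camera adjusted p = 0.0774). The list was called higher in 3 of 9 alternatives, with scaling to the median (adjusted p = 6.67e-04), with no filter on dim probes and with scaling to the spike-ins, and its adjusted p reached 0.246 in the others. Of 17 tested, 6 rose and 1 fell, 7 when adjusted over the list alone. Beside GNE, the sialyltransferase gene ST6GAL2 was at least 34.2-fold higher (adjusted p = 1.93e-08), and ST3GAL5 (1.45 ± 0.21), ST3GAL1 (1.40 ± 0.60) and ST6GAL1 (1.12 ± 0.18) rose. ST6GALNAC4 fell (-0.90 ± 0.35), and the probes of ST6GALNAC6 disagreed in sign (1.02 and -0.73). NEU1, a lysosomal sialidase and the only sialidase gene tested, fell by 1.97 (SD 0.31). Other glycan synthesis genes went both ways, with 8 of 24 higher and 5 lower (camera adjusted p = 0.616; 15 adjusted over the list alone), including UGT8 (1.57 ± 0.24) and MGAT5 (-1.89 ± 0.04). Of 22 heparan sulfate genes, 6 rose and 4 fell (camera adjusted p = 0.781; 10 adjusted over the list alone), and the sulfatase gene SULF2 (-2.01 ± 0.09) and GPC1 (-1.95 ± 0.06) fell most.

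Of 11 ribonuclease and ribonuclease inhibitor genes, 1 rose and 2 fell (camera adjusted p = 0.849; 2 adjusted over the list alone). DROSHA, which processes microRNA precursors, fell (-0.40 ± 0.11) and SLFN11, which cleaves tRNA, was at least 2.20-fold lower. Genes of ATF4 and the unfolded protein response included 9 that rose and 3 that fell of 24 (camera adjusted p = 0.0582; 14 adjusted over the list alone). The list was called higher with quantile normalization, with or without normexp background, and with no filter (adjusted p from 0.0361 to 0.436 over the alternatives). The chaperone genes CALR (0.96 ± 0.01), PDIA4 (0.88 ± 0.11) and HSP90B1 (0.81 ± 0.05) rose, and the amino acid synthesis gene ASNS fell (-0.62 ± 0.17).

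Receptor ligand genes were higher as a list (camera adjusted p = 0.014; adjusted p = 0.787 with an estimated correlation), with 8 of 15 higher and 1 lower, and 10 adjusted over the list alone. Beside IGF2 and AREG, the ligand genes BTC (1.92 ± 0.01), FGF2 (1.21 ± 0.05) and PDGFC (1.17 ± 0.15) rose, HBEGF was at least 3.46-fold higher, and EREG was at least 5.27-fold lower. Receptor tyrosine kinase genes went both ways, with 9 of 20 higher and 4 lower (camera adjusted p = 0.161, and 0.0334 with no filter on dim probes; 14 adjusted over the list alone). FGFR2 (4.40 in A1 and 3.59 in B1), ROR1 (2.18 ± 0.09), ERBB4 (2.09 ± 0.12) and DDR1 (1.84 ± 0.09) rose, IGF1R (-1.66 ± 0.04), INSR (-1.34 ± 0.30) and MET (-1.20 ± 0.80) fell, and DDR2 was at least 14.6-fold lower.

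Cytokine genes that NF-kB can activate were higher as a list (camera adjusted p = 0.0109; adjusted p = 0.787 with an estimated correlation), with 8 of 16 higher, 2 lower and 11 adjusted over the list alone. CXCL1 rose (4.05 ± 0.62) beside CCL2 and ICAM1, CXCL8 was at least 4.04-fold higher, and SOD2 fell (-0.60 ± 0.12). The calls of this list and of the ligand list were lost when the median of each gene's 41 neighbours on the chromosome was subtracted (adjusted p = 0.126 and 0.166), a setting chosen after seeing the data, and that of the ligand list also with quantile normalization and with the authors' deposited table.

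The list of YAP and TEAD targets was higher (camera adjusted p = 5.58e-06, and 0.787 with an estimated correlation). It also holds the regulators themselves, YAP1, WWTR1, TEAD1 and TEAD4. Of 17 members tested, 14 rose, these regulators among them, and 1 fell, with 15 adjusted over the list alone. CCN2 (2.51 ± 0.19), IGFBP3 (1.74 ± 0.62) and ARHGEF17 (1.31 ± 0.01) rose and ANKRD1 fell (-1.89 ± 1.34). The probes of WWTR1 disagreed in sign (1.04 and -2.53). Genes of the TGF-beta and BMP pathways were higher (camera adjusted p = 0.0109; adjusted p = 0.787 with an estimated correlation), with 6 of 15 higher, 2 lower and 9 adjusted over the list alone. INHBB (3.47 ± 0.07) and BMP2 (1.91 ± 0.23) rose, BMP6 fell (-1.11 ± 0.17), and TGFB2 was at least 1.40-fold lower; the call was lost with scaling to the spike-ins (adjusted p = 0.16).

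Epithelial markers were higher (camera adjusted p = 0.00569; adjusted p = 0.787 with an estimated correlation), with 8 of 14 higher and 1 lower, and 9 adjusted over the list alone. EPCAM (2.98 ± 0.17), MUC1 (2.03 ± 0.03) and the keratin gene KRT8 (1.30 ± 0.23) rose. Mesenchymal genes were lower (camera adjusted p = 0.0296; adjusted p = 0.787 with an estimated correlation), with 6 of 13 lower and 1 higher, and 9 adjusted over the list alone. TGFBI (-2.10 ± 0.39) fell, FN1 was at least 3.15-fold lower, and SNAI1, a repressor of epithelial genes, rose (2.67 ± 0.03). The median of the list was -0.51 in A1 and -0.93 in B1. This call was lost in 3 of 9 alternatives (adjusted p up to 0.0795). Mesothelial markers were not called (camera adjusted p = 0.37), with 6 of 13 higher, 3 lower and 10 adjusted over the list alone. UPK1B (2.31 ± 0.65), WT1 (2.02 ± 0.36) and LRRN4 (1.52 ± 0.15) were among those that rose, and SPP1, TGM1 and THBD fell. The mesothelial list was called higher among genes above background on all 3 arrays (adjusted p = 0.0243) and in no other alternative (adjusted p up to 0.594).

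**Figure D2:**
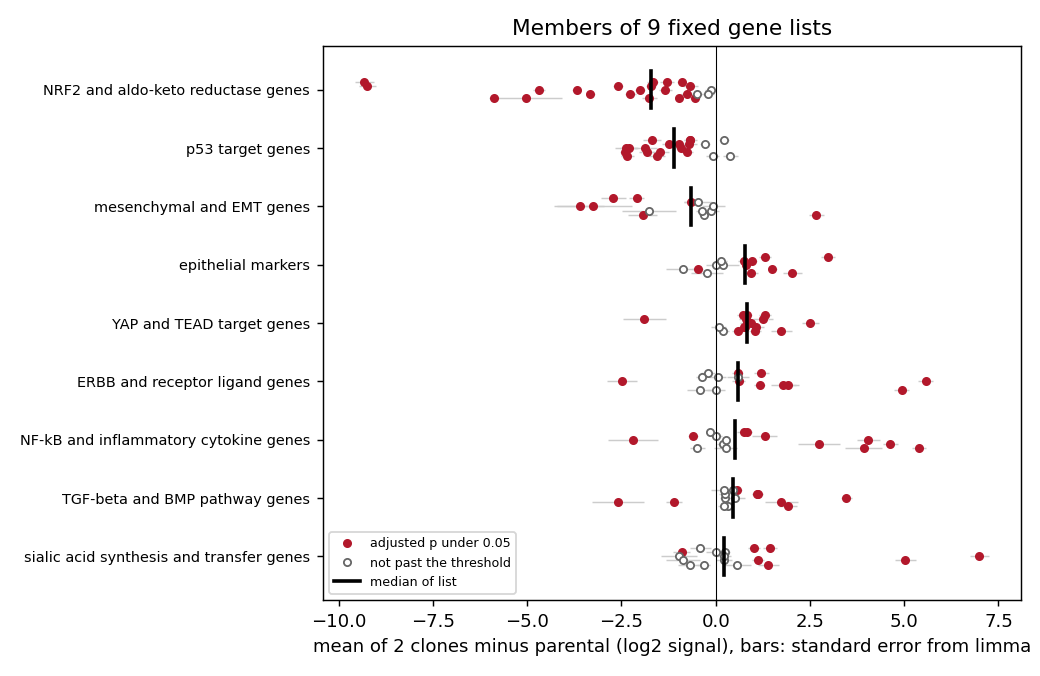
Mean log2 difference, resistant minus parental, of the tested members of 9 gene lists, 1 point per gene, with bars for limma's SE and a black line for the median of the list. Red points passed the adjusted threshold of 0.05; the NRF2 list has the lowest median, -1.72, and signals of genes not well above background enter as measured.

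Some further lists were called whose calls were lost in most alternatives: hypoxia was called in 4 of 9, metallothioneins in 3 and ribosomal proteins in 1. Hypoxia and glycolysis genes were lower (camera adjusted p = 0.018; adjusted p = 0.787 with an estimated correlation), with 8 of 17 lower, 0 higher and 10 adjusted over the list alone, including EGLN3 (-2.11 ± 0.05). Metallothionein genes, which bind metals, were higher (camera adjusted p = 0.0443; adjusted p = 0.787 with an estimated correlation), with 2 of 8 higher and 5 adjusted over the list alone, and MT1F rose (1.86 ± 0.05). The median of the metallothionein list was 0.27 in A1, at percentile 95.2 of random lists, and 1.29 in B1, at percentile 100. Ribosomal protein genes had a median of -0.18 (camera adjusted p = 0.0302; adjusted p = 0.787 with an estimated correlation), which turned to 0.01 with quantile normalization, with or without normexp background, and to 0.21 with scaling to the spike-ins. Of 30 tested, 7 fell and 1 rose, 7 adjusted over the list alone.

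Markers of other cell types were sparse. Of fibroblast markers 3 of 12 were tested, and THY1 and DCN, the latter at least 1.78-fold, were lower in the clones (camera adjusted p = 0.0603). This list was called lower with scaling to the median (adjusted p = 4.72e-09) and to the spike-ins (adjusted p = 7.64e-13), and in none of the other 7 alternatives (adjusted p up to 0.972). None of the 5 leukocyte markers tested was called by limma. Of 3 endothelial markers EGFL7 rose (0.58 ± 0.12), and of 5 red cell and liver markers 2 rose and 1 fell, among them SERPINA1 (1.18 ± 0.49) and HBG1 (-0.98 ± 0.31).

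The second comparison set the clones against each other, with 1 array each and no replicate check. ABCC2, an efflux transporter gene, was 11.9-fold higher in B1 than in A1, and TRIM7 6.19-fold, CA12 3.85-fold, SPANXA1 3.36-fold, JCAD 3.32-fold, GNA15 3.25-fold, CD109 3.01-fold and BEND7 2.97-fold. UCKL1-AS1 was 6.94-fold higher in A1, ANO9 6.05-fold, MAT1A 4.21-fold, ECHDC2 4.16-fold, ARHGAP45 3.84-fold, ANKRD1 3.73-fold, LOC101928087 3.35-fold and SLC17A4 3.31-fold. Among genes measured in 1 clone, IKZF2 was at least 10.3-fold, SCAT1 at least 5.84-fold and PCDHGA5 at least 5.70-fold higher in B1, and NEK5 at least 6.61-fold, SMC5-DT at least 4.95-fold and VIL1 at least 4.51-fold higher in A1. Of 15354 genes compared, 566 differed by at least 2-fold, 331 higher in A1 and 235 higher in B1, a split that turned to 254 and 302 with scaling to the median. This count fell to 62 with normexp background and quantile normalization and to 144 among genes above background on all 3 arrays.

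Genes were also ordered along the chromosomes in 732 overlapping windows of 40 neighbours, 15340 genes in all. In 37 windows the median of both clones lay beyond the 95th percentile of the permuted maximum, 15 higher and 22 lower, all relative to the median of all genes. A run on chromosome 4 from 52.8 to 186.1 Mb, with 320 genes, had a median difference of 0.65 in A1 and 0.80 in B1. The genes on chromosome 5 from 53.8 to 121.4 Mb had medians of -0.88 and -0.74. Those on chromosome 3 from 1.45 to 24.0 Mb had medians of -0.73 and -0.65, and from 48.6 to 69.0 Mb of -0.58 and -0.58. In this order, these runs held 14, 9, 4 and 6 of the 37 windows, which overlap and rest on the same parental array. Between the clones, 16 windows lay beyond the permuted maximum, 12 of them on chromosome 13 from 19.3 to 115 Mb, where A1 was higher by a median of 0.29. AREG, on chromosome 4 at 75320518 to 75320577, lies in the run on chromosome 4. The other members of the ligand and NF-kB lists were not placed in these runs. Both lists lost their calls when the neighbouring genes' median was subtracted, so those calls may rest in part on such runs.

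**Figure D3:**
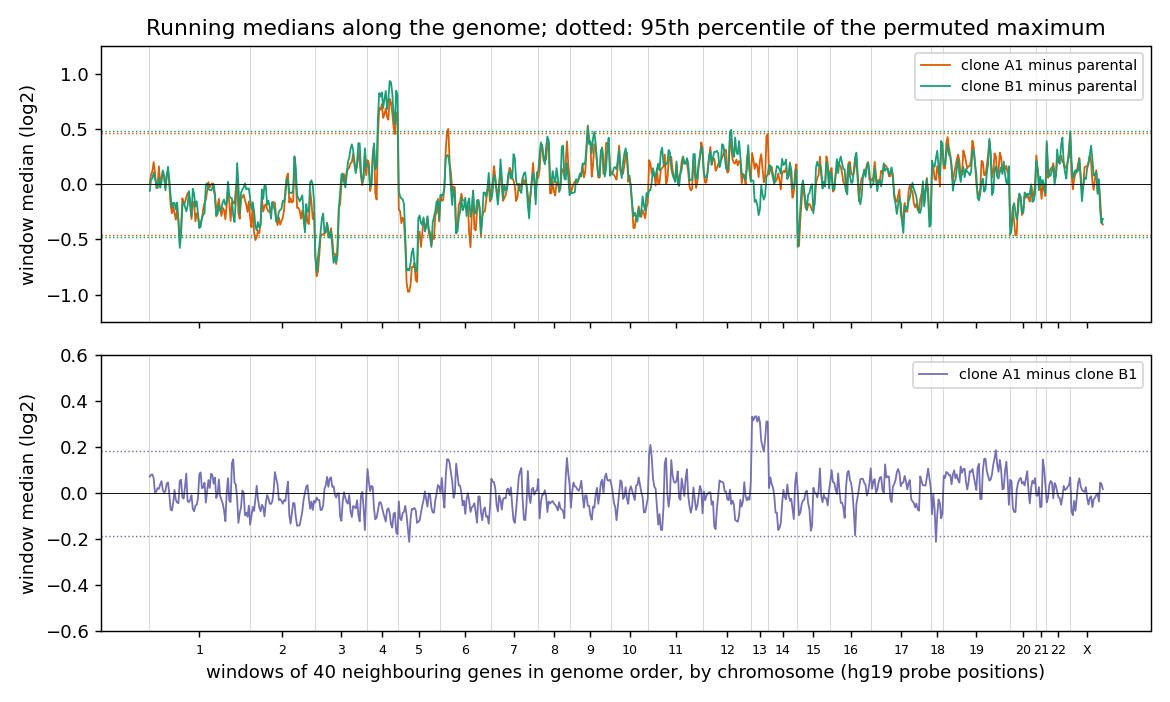
Median log2 difference in overlapping windows of 40 neighbouring genes along chromosomes 1 to 22 and X (hg19 order), centred on all genes. Each clone minus parental is above and clone A1 minus clone B1 below. Dotted lines mark the 95th percentile of the permuted maximum, at 0.46, 0.48 and 0.18; the runs on chromosomes 3, 4 and 5 appear in both clones and the run on chromosome 13 between them.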

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

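A signal appeared in probes that carry no gene name, which entered none of the gene comparisons above. Of 5888 such probes well above background in a group, 232 were at least 2-fold higher in both clones and 516 were at least 2-fold lower. By the same rule 1006 of the 15393 genes tested were higher and 1053 lower. Of the unnamed probes, 274 were well above background on both clone arrays and not on the parental array, and 602 only on the parental array. No explanation was tested.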

How the results depend on the processing

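The alternatives named here as added were chosen after seeing the data. The count of 5169 called genes fell to 2951 without the trend, and with every probe tested on its own, named or not, 7797 probes were called; among added settings it fell to 1325 with scaling to the spike-ins, 1386 with 4 times the variance for the parental array and 717 in a test against a 2-fold difference. Scaling to the spike-ins also moved the median of all genes to 0.36 and the share of calls that were higher from 49.2% to 69.1%; genes lower by less than this shift turn upward under it. With the other scalings, normexp and the deposited table, all set beforehand, the calls numbered 3506 to 4277. An added 75th percentile over probes above background on all arrays gave 4670. Of 4109 calls with the median, 3894 were shared with those reported, and 3696 of 3754 with the authors' deposited table.

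The 2059 genes at least 2-fold different in both clones became 1043 with normexp background and quantile normalization, 4222 at 1.5-fold and 629 at 4-fold. For A1, 2768 became 1324 with normexp, 1843 above background on all 3 arrays, 5481 at 1.5-fold and 904 at 4-fold, and for B1, 2835 became 1295, 1833, 5605 and 916. Between the clones, 566 became 62 with normexp, 1694 with no filter on dim probes, 144 above background on all 3 arrays, 1388 at 1.5-fold and 167 at 4-fold. The correlation of 0.933 became 0.948 with normexp and 0.833 with no filter. The 11 called lists became 7 with quantile normalization, 6 with the authors' deposited table, 7 after subtracting the neighbouring genes' median (added), 0 with an estimated correlation and 0 with fry. Stricter filters and folds count fewer genes by construction. The offset of 50 in normexp shrinks the log2 differences of dim probes by construction too, where the arrays' median processed signals were 13.7 to 15.7. How much of the falls with normexp this covers was not tested. Camera with an estimated correlation and fry could hardly call a list on 1 residual degree of freedom. Otherwise the cause was not tested.

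There were 9 alternatives for the values, of which 2 were added. The NRF2, p53, epithelial, and YAP and TEAD lists were called in each by camera with its preset correlation. In each, the NRF2 list held the aldo-keto reductases that were listed with knowledge of the study. The NF-kB and TGF-beta lists were called in 8, the ligand and mesenchymal lists in 6, hypoxia in 4, metallothioneins in 3 and ribosomal proteins in 1. With an estimated correlation and with fry all these lists lost their calls, but both tests rest on 1 residual degree of freedom. The NRF2 list, with the lowest camera p, had unadjusted p-values of 0.0654 (camera, estimated correlation) and 0.00796 (fry). The loss of calls there thus says little either way. The ribonuclease, heparan sulfate, cyclin, interferon, mesothelioma tumour suppressor, lipid and red cell lists had medians and means of opposite sign. Among 352 named genes and called list members, 2110 of 2424 values tested in other choices of scaling, background, filter, probe rule or deposited table set beforehand stayed past the threshold in their direction, 313 lost the call and 1 reversed: WWTR1 stood at -0.74 (adjusted p = 0.0276) with the mean of its probes. None of the genes named by rank lost its call where one of these tested it. With each clone left out, all 704 values of the 352 genes kept their direction. This follows from the choice of genes and is no separate check, since 100% of called genes had the same sign in both clones. Leaving out a clone gave 2608 to 2649 genes at least 2-fold different; without either clone the limma fit has no residual degrees of freedom, so calls and list tests have no such value. No paired analysis was possible because the parental group has 1 sample. Signal over background limits dim genes: with no filter, 23702 genes were tested and 6312 called.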

Other observations

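The tests of aldo-keto reductase paralogs, of the cell line and of subtracted neighbouring genes, and cyclic loess for the 2-fold count, were chosen only after the result was seen. Several lists not called by camera held large changes in both directions. Of 16 matrix metalloproteinase and inhibitor genes, 7 rose and 3 fell (camera adjusted p = 0.252): the urokinase receptor gene PLAUR (2.29 ± 0.21, SD, n = 2) and TIMP2 (1.22 ± 0.14) rose, PLAT was at least 9.87-fold and TIMP3 at least 7.77-fold higher, MMP7 fell (-2.45 ± 0.05), and MMP1 was at least 8.72-fold lower. Of 23 integrin and laminin genes, 6 rose and 5 fell (camera adjusted p = 0.307, and 0.00202 with no filter on dim probes), with ITGB8 (3.07 ± 0.08) and ITGAV (1.28 ± 0.11) higher and ITGB6 at least 4.26-fold lower. Of 12 collagen genes, 5 rose and 3 fell (camera adjusted p = 0.44), with COL12A1 (2.78 ± 0.22) and COL4A1 (1.54 ± 0.32) higher.

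Interferon-stimulated genes included 9 higher and 5 lower of 21 (camera adjusted p = 0.3, upward, although the median was -0.08). This list was called higher with scaling to the median (adjusted p = 0.0167) and to the spike-ins (adjusted p = 0.00903), and in no other alternative (adjusted p up to 0.632). IFITM1 (4.53 ± 0.20), IRF7 (4.03 ± 0.82) and BST2 (2.27 ± 0.56) rose, whereas ISG15 (-1.08 ± 0.13) fell. Of 14 WNT pathway genes, 5 rose and 3 fell (camera adjusted p = 0.487), with WNT10A (2.35 ± 0.67) higher and RSPO3 (-2.03 ± 0.00) lower. Among 13 G1 cyclin and CDK inhibitor genes (camera adjusted p = 0.542), CDKN1C (1.86 ± 0.09) and CDKN1B (1.11 ± 0.04) rose, CCND3 fell (-1.42 ± 0.08), and CCND2 was at least 4.42-fold lower. The lipid regulator PPARG fell (-2.60 ± 0.04) in a list of 13 with 4 higher and 4 lower (camera adjusted p = 0.849). Adjusted over the list alone, 12 metalloproteinase, 11 integrin, 8 collagen, 14 interferon, 8 WNT, 7 cyclin and 8 lipid genes passed. Of 22 genes of the JNK and p38 response, 8 rose and 1 fell (camera adjusted p = 0.112; 9 adjusted over the list alone), the latter being the phosphatase gene DUSP4 (-1.04 ± 0.11). Heat shock protein genes included 2 higher and 5 lower of 20 (camera adjusted p = 0.252, and 0.00241 with no filter on dim probes; 9 adjusted over the list alone). Mucin genes had 3 higher and 2 lower of 13, cholesterol synthesis genes 3 and 3 of 17, and ABC transporter genes 3 and 3 of 14 (camera adjusted p = 0.542 each; 5, 6 and 8 adjusted over the list alone).

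Many genes differed between the parental array and both clones. Against labelling or hybridization that acts unevenly on probes, the 7 spike-in probes above background on all arrays varied by 0.0726 times as much as the genes. Each of these probes had 35 spots. The ratio leaves out a shift common to them, whose medians were -0.20 in A1 and -0.59 in B1. It therefore does not test RNA input or quality. Against an intensity trend, 97.3% of the 2-fold genes stayed so after cyclic loess. With 1 parental array, resistance, clone selection and the state of the parental culture cannot be told apart, nor can a response to lectin present at RNA extraction, which the labels leave open. Arrays of different cell lines stay open too: CTNNB1, known to be deleted in H28, was well above background on 0 of 3 arrays, and although that was the outcome set for a shared line, 1 gene near the floor excludes nothing.

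Aldo-keto reductase and NRF2 genes were lower in both clones. Signal shared between paralogs is argued against as the whole cause by the 17 members outside the family, whose median was -1.29, with 14 called lower. A candidate explanation is lower NRF2 activity in the clones: a separate list of further NRF2 targets, written before its test, had medians of -1.24 in A1 and -1.09 in B1, at percentile 0 of 10000 random lists in each, with 20 of 23 called lower and 0 higher. High NRF2 activity in this parental culture alone would look the same and was not tested.

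Neighbouring genes differed together in 37 overlapping windows in both clones, read against the same parental array, as chromosomal gains or losses would give. Clusters of paralogs do not account for it, since the windows kept 100.4% of their shift (median over windows) without genes that share a symbol stem. A candidate explanation is a difference in chromosome content shared by the clones, as in the run on chromosome 4, with a further one on chromosome 13 between them. In the run on chromosome 4, 82.8% of genes lay higher. Its windows were picked for their medians in the same values, so that share is no separate support. DNA was not analysed here, and regulation across whole regions was not tested. With the neighbouring genes' median subtracted, 1866 genes differed by at least 2-fold in both clones, against 2059 without.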
